A study of Mus musculus with 24 samples.

How the data were processed

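Per the submitters' processing notes, the authors aligned reads to GRCm38 with HISAT2 2.0.5, quantified genes with RSEM 1.3.0, kept genes above a mean TPM limit and tested them with DESeq2. The 7 files held the authors' result tables: a mean normalized level (read as a signal, per the file headers), a log2 fold change and its standard error (both in log2 units, per the file headers), a Wald score (per the file headers) and a p-value and adjusted p-value (as deposited), with a symbol and coordinates. The Wald score equalled the deposited fold change over its standard error in every gene, so the fold changes were read as unshrunken. Values per library were not analysed here. The plan made before the data were examined assumed a count for each library. As the unit differed from that plan, the edgeR test it named was not used, and the planned fallback, the authors' own adjusted p-values, served for the calls. Sample groups followed the labels: genotype and sgRNA, 3 libraries in each of 8 groups. The replicate numbers were not used.

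The mean level of a gene was the same in the 3 knockdown tables of a genotype, so each genotype had been fitted with its 12 libraries together, and the level of each group was calculated back from that mean and the fold changes. Checked on simulated data, the median error of this step was 0.000873 log2 units. The Het and WT table matched the scramble libraries: its fold changes correlated across genes at r 0.991 with those calculated back from the scramble groups, against 0.936 for all 12 libraries of each genotype.

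A gene was called changed at the deposited adjusted p below 0.05. Genes to which the authors gave no adjusted p were not called. Of 21210 genes in any table, 21175 were found in the GENCODE M21 annotation of GRCm38 used for exon number, gene class, length and GC content. The difference of a knockdown effect between genotypes was the Het minus the WT log2 fold change, divided by the root of the summed squared standard errors, with p from the normal distribution, adjusted after Benjamini and Hochberg over 19165 genes. In simulated data with 200 of 11101 genes changed 2-fold this test called 86.5% of them, and 2.81% of its calls were false.

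The 35 gene lists, 1064 entries written before the data were examined, covered EJC and NMD factors, NMD-sensitive transcripts, splicing factors, the ATF4 response, p53 targets, adhesion, extracellular matrix, autophagy and lysosome, mitochondrial chaperones, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, BCL2 family and caspases, translation initiation, ribosomal proteins, ribosome biogenesis and MYC targets, G1/S, G2/M, interferon, NF-kB, RAS-MAPK output, cholesterol, hypoxia and glycolysis, ER chaperones, heat shock, NRF2, histones, TGF-beta, YAP/TAZ and markers of fibroblasts, epithelium, immune cells, endothelium, muscle, neural and glial cells, and cartilage and fat. Each was tested against all other genes with cameraPR of limma 3.58.1 on the deposited Wald score, with a preset correlation of 0.01 and adjustment over the 35 lists of a comparison. Simulated without the data's gene correlation, 4.5% of unchanged and 100% of 1 SD shifted lists had p below 0.05. Epithelial results of 4 knockdowns with a single called gene are left out. Counts adjusted over the list alone used its members' deposited p-values only.

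Named genes followed a rule set before the data were examined: the targets, Magohb and Eif4e; the 8 called genes with the largest rise and the 8 with the largest fall at a mean of at least 5 in the higher group, without predicted genes; up to 4 genes per list by adjusted p; 5 genes each way per difference between genotypes; and 8 each way that changed with all 3 sgRNAs. The part of the rule that asks for separated replicates could not be applied. The neighbour of Rbm8a, Ephx1, Npc1, Srsf6 and other list members that moved against their list, genes that set the genotypes apart in several comparisons and the grouping by exon number and chromosome were chosen after the values had been seen.

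Overlaps are given beside the count expected of independent draws and the mean of 100 simulations of groups without any effect that share their scramble libraries. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. The alternatives tried were another filter on level, centring of each table, genes tested in all tables only, centring by chromosome, a preset correlation of 0.05, lists without the targeted genes and removal of the exon trend. Splicing, allele and isoform questions were left out, as the tables hold 1 value per gene.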

Results

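RNA was sequenced from mouse embryonic fibroblasts (MEFs), connective-tissue cells grown from mouse embryos, that had been immortalized and expressed Myc and Ras. Some cells carried both copies of Eif4e, the gene of the protein that binds the mRNA cap at the start of translation (WT), and others a single intact copy (Het). All expressed dCas9-KRAB, a cutting-dead Cas9 fused to a repressor of transcription, which a single guide RNA (sgRNA) directs to a promoter, and doxycycline at 0.4 ug/ml was given for 48 h. The sgRNAs were a scramble control or targeted Eif4a3, Magoh or Rbm8a, whose proteins form the core of the exon junction complex (EJC), the protein complex that splicing leaves on mRNA upstream of exon junctions and that takes part in nonsense-mediated decay (NMD), the destruction of mRNAs with a premature stop codon. There were 3 libraries of ribosomal-RNA-depleted total RNA in each of 8 groups, 24 in all. Every value below comes from 7 tables of fold changes between groups made by the submitters. The tables held 20759 genes for the WT knockdowns, 19616 for the Het knockdowns and 14972 for Het against WT, with summed mean normalized counts of 1.86e+07, 1.46e+07 and 1.37e+07, and the depth of single libraries is unknown. The 6 knockdown comparisons asked what lowering each EJC protein did in each genotype, the Het against WT scramble comparison asked how the genotypes differed before knockdown, and 3 differences of differences asked whether a knockdown acted differently in the genotypes. A gene is called changed where its adjusted p was below 0.05, values are log2 fold changes ± the table's standard error, list p is the adjusted p of the test of a gene list with the correlation between its genes preset at 0.01 (where a preset of 0.05 ended a call, the list p there follows), and p-values measure only the spread among these libraries, since the labels do not say whether replicates were separate cultures.

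The targeted genes were lowered in both genotypes. Eif4a3, encoding the EJC helicase (GRCm38 chromosome 11, 119288363 to 119300089, minus strand), stood at 40.3% of its scramble level in WT and 31.0% in Het cells with its own sgRNA, and the authors' deposited table gave -1.31 ± 0.07 (adjusted p 3.35e-79) and -1.69 ± 0.08 (adjusted p 7.55e-108). Magoh (chromosome 4, 107879755 to 107887424, plus strand) stood at 24.8% and 24.4%, or -2.01 ± 0.08 and -2.03 ± 0.08 in the authors' deposited table (adjusted p 1.97e-147 and 7.34e-132). Rbm8a, which encodes the MAGOH partner Y14 (chromosome 3, 96629933 to 96633791, plus strand), stood at 22.7% and 24.3%, or -2.14 ± 0.10 and -2.04 ± 0.09 in the authors' deposited table (adjusted p 1.20e-97 and 8.99e-110). Eif4e (chromosome 3, 138526179 to 138559696, plus strand) was 77.0% of the WT level in Het scramble cells, -0.38 ± 0.07 in the authors' deposited table (adjusted p 6.86e-06). It also fell in all 6 knockdowns, with values of -0.30, -0.37 and -0.26 in WT and -0.28, -0.31 and -0.18 in Het cells in the order Eif4a3, Magoh, Rbm8a, as the authors' deposited table has it. Magohb, the paralogue of Magoh (chromosome 6, 131284388 to 131293244, minus strand), rose by 0.79 ± 0.32 and 1.23 ± 0.31 with the Eif4a3 and Magoh sgRNAs in Het cells in the authors' deposited table, where it was 3.40 ± 0.90 higher in Het than in WT scramble cells (adjusted p 0.00216) and had 2.04 ± 0.83 with the Eif4a3 sgRNA in WT cells (no adjusted p). Magoh rose by 0.28 ± 0.07 with the Eif4a3 and 0.29 ± 0.07 with the Rbm8a sgRNA in Het cells in the authors' deposited table. The nearest neighbour of a target, 6330549D23Rik, starts 113 bp from Rbm8a and had -1.47 ± 0.46 in Het (adjusted p 0.00724) and -0.76 ± 0.42 in WT cells with the Rbm8a sgRNA in the authors' deposited table. Casc3, the fourth EJC protein, and Trp53 were called in none of the 7 comparisons.

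**Figure D1:**
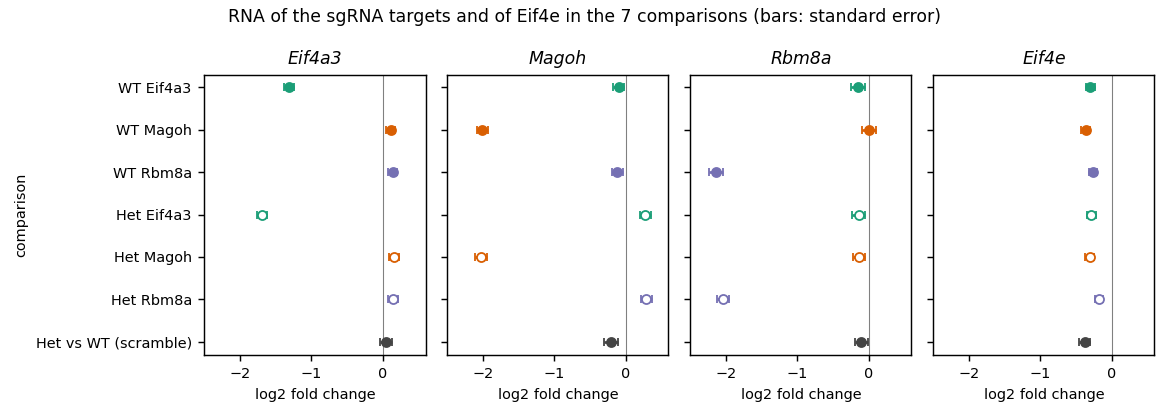
Log2 fold change (x axis) of Eif4a3, Magoh, Rbm8a and Eif4e (panels) in the 7 comparisons (y axis). Points are the values of the authors' deposited table and bars ± its standard error.

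Lowering Eif4a3 in WT cells raised stress-response and lysosomal genes and lowered genes of adhesion and lipid synthesis. The stress transcription factor gene Ddit3 rose by 1.81 ± 0.10 and Trib3, the gene of a pseudokinase that Ddit3 and Atf4 induce, by 1.77 ± 0.20 in the authors' deposited table. Further large rises there, all in the authors' deposited table, were those of Adnp (2.61 ± 0.51), Cnbd2 (1.94 ± 0.21), the kinase-anchoring gene Akap5 (1.79 ± 0.27), the ATP-gated channel gene P2rx7 (1.78 ± 0.31), the lysosomal glycoprotein gene Cd68 (1.68 ± 0.23) and the tubulin-modifying Ttll3 (1.64 ± 0.29). Eif4a2, a paralogue of the target that serves in translation initiation, rose by 1.27 ± 0.06 in the authors' deposited table. The largest falls in the authors' deposited table were those of the glycosyltransferase gene Mgat3 (-1.87 ± 0.34), Pakap (-1.75 ± 0.66), the formin gene Fhod3 (-1.61 ± 0.30), the complement protease gene C1s1 (-1.53 ± 0.22), Gprin3 (-1.44 ± 0.20), the matrix proteoglycan gene Ogn (-1.41 ± 0.25), the semaphorin receptor gene Plxna3 (-1.40 ± 0.21) and the immediate-early gene Fos (-1.37 ± 0.28). Of 13514 genes tested, 2077 were called higher and 2327 lower, and 323 of these changed at least 2-fold. With each table centred on its median, more genes were higher (2265) than lower (2117) here, as in all other knockdowns but WT Rbm8a.

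With the Magoh sgRNA in WT cells, Mx2, P2rx7 and Ddit3 rose while Ccnd1, Fos and Fosb fell. The authors' deposited table gave rises of 2.35 ± 0.30 for the antiviral gene Mx2, 1.94 ± 0.31 for P2rx7, 1.94 ± 0.27 for Akap5, 1.84 ± 0.32 for the ER-shaping gene Reep1, 1.84 ± 0.21 for Cnbd2, 2.13 ± 0.51 for Adnp and 3.32 ± 0.40 for Txndc2. Eif4a2 rose by 1.53 ± 0.06, Ddit3 by 1.71 ± 0.10 and the snoRNA host gene Snhg15 by 1.47 ± 0.09 in the authors' deposited table. The largest value, 6.51 ± 2.26 for the mitochondrial mt-Co2, carried a wide standard error in the authors' deposited table, and -0.99 ± 2.34 and -1.97 ± 2.34 with the other sgRNAs were not called. Falls in the authors' deposited table included those of the ciliary transport gene Ift140 (-1.70 ± 0.15), Plxna3 (-1.68 ± 0.21), Fos (-1.43 ± 0.27), Fosb (-1.24 ± 0.22), the cyclin D1 gene Ccnd1 (-1.31 ± 0.09), the RNA helicase gene Mov10 (-1.27 ± 0.16), the purine synthesis gene Pfas (-1.25 ± 0.08) and Rapgef3 (-1.23 ± 0.22). Among 13514 genes tested, 2237 were called higher and 2407 lower, 357 of them by at least 2-fold.

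The Rbm8a sgRNA gave smaller changes in WT cells. In the authors' deposited table Eif4a2 rose by 1.16 ± 0.06, Snhg15 by 0.97 ± 0.09, Mx2 by 1.50 ± 0.30, the interferon-induced Oas1b by 1.03 ± 0.27, Cd68 by 1.04 ± 0.24, Cnbd2 by 1.10 ± 0.22, the mucin gene Muc13 by 0.96 ± 0.26 and Adnp by 2.18 ± 0.51. The falls were led, in the authors' deposited table, by Ccnd1 (-0.92 ± 0.09), the matrix proteoglycan gene Bgn (-0.92 ± 0.13), the adenylate kinase gene Ak5 (-0.90 ± 0.24), Ift140 (-0.88 ± 0.15), Plxna3 (-0.78 ± 0.21), the glucose-6-phosphatase gene G6pc3 (-0.76 ± 0.26), Fosb (-0.74 ± 0.22) and the proteasome activator gene Psme4 (-0.72 ± 0.07). Ddit3 (0.83 ± 0.10) and Trib3 (0.71 ± 0.20) rose in the authors' deposited table, while Mov10 (-0.38 ± 0.16) and Fos (-0.47 ± 0.27) were not called. Of 10697 genes tested, 601 were called higher and 917 lower, 18 of them by at least 2-fold. With measurement error removed, the standard deviation of the fold changes of 7907 well-expressed genes was 0.162 with this sgRNA, against 0.289 for Eif4a3 and 0.317 for Magoh.

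In Het cells the Eif4a3 sgRNA raised Ddit3 by 2.26 ± 0.10 and the interferon-induced chemokine gene Cxcl10 by 2.09 ± 0.31 in the authors' deposited table, where Ccnd1 (-1.80 ± 0.08) fell. Akap5 (2.66 ± 0.31), Reep1 (2.30 ± 0.29), the sarcomere gene Myom1 (2.29 ± 0.33), Aloxe3 (2.05 ± 0.27), Txndc2 (2.90 ± 0.39) and the low-count Olfr461 (4.13 ± 0.48) made up the other large rises in the authors' deposited table. Falls in the authors' deposited table were those of the transcription cofactor gene Eya2 (-2.78 ± 0.41), Park2, the gene of the ubiquitin ligase parkin (-2.86 ± 0.84), the surface antigen genes Ly6a (-1.99 ± 0.31) and Ly6c1 (-1.91 ± 0.33), Plxna3 (-1.84 ± 0.27) and the outer mitochondrial membrane gene Tspo (-1.76 ± 0.17). The histone gene Hist2h2aa2 had -20.05 ± 4.35 in the authors' deposited table, a size that arises when a group holds no reads, and is not read as a measured fold change. Of 16193 genes tested, 2639 were called higher and 2869 lower, and 790 changed at least 2-fold.

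Lowering Magoh in Het cells raised Mx2 by 1.94 ± 0.15, Cxcl10 by 1.88 ± 0.31 and Snhg15 by 1.81 ± 0.11 in the authors' deposited table. Txndc2 (2.91 ± 0.39), the DNA polymerase gene Poln (2.63 ± 0.36), the sperm channel gene Catsper2 (2.50 ± 0.36), Akap5 (2.38 ± 0.31) and Reep1 (1.99 ± 0.29) rose there too in the authors' deposited table. The junctional protein gene Ppl (-2.20 ± 0.20), the glycosyltransferase gene Gcnt4 (-2.10 ± 0.31), Ndrg2 (-2.04 ± 0.31), Ccnd1 (-1.99 ± 0.09), the potassium channel gene Kcnn4 (-1.98 ± 0.28), Eya2 (-3.18 ± 0.44) and Park2 (-2.07 ± 0.82) fell in the authors' deposited table, in which Hist2h2aa2 again had an unmeasurable -26.95 ± 4.35. Among 15052 genes tested, 2163 were called higher and 2506 lower, and 610 changed at least 2-fold.

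Lowering Rbm8a in Het cells raised Eif4a2 by 1.50 ± 0.07, Snhg15 by 1.58 ± 0.11, the long noncoding RNA gene Pvt1 by 1.54 ± 0.13, the nuclear receptor gene Rora by 1.48 ± 0.16, Magef1 by 1.56 ± 0.23, Cnbd2 by 1.65 ± 0.23, Akap5 by 2.05 ± 0.31 and Reep1 by 2.04 ± 0.29 in the authors' deposited table. The water channel gene Aqp1 (-2.12 ± 0.34), Ppl (-1.66 ± 0.19), Ndrg2 (-1.51 ± 0.29), Ly6a (-1.50 ± 0.30), Eya2 (-2.91 ± 0.42), Park2 (-2.89 ± 0.84) and the small nucleolar RNA gene Snora74a (-1.54 ± 0.57) fell in the authors' deposited table, which held an unmeasurable -26.58 ± 4.35 for Hist2h2aa2. Of 13151 genes tested, 1807 were called higher and 1949 lower, and 344 changed at least 2-fold.

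Many genes changed the same way with all 3 sgRNAs. In WT cells these included, in the authors' deposited table and in the order Eif4a3, Magoh, Rbm8a, Oas1b (1.32, 1.66 and 1.03), P2rx7 (1.78, 1.94 and 1.17), Psme4 (-1.09, -1.13 and -0.72), the folate enzyme gene Mthfd1 (-0.87, -1.18 and -0.71), Gcnt4 (-0.71, -1.07 and -0.68) and Ak5 (-0.73, -0.84 and -0.90). In Het cells they included Catsper2 (2.37, 2.50 and 2.04), Poln (1.97, 2.63 and 2.19), Olfr461 (4.13, 3.84 and 3.61) and the laminin gene Lama5 (-1.50, -1.52 and -1.35), again from the authors' deposited table. WT cells had 556 genes higher and 782 lower in all 3 comparisons, 1338 of 10697 genes, against 62.9 for independent comparisons. Het cells had 1469 higher and 1597 lower, 3066 of 13151 genes, against 136. Of the 556 and 781 genes higher and lower in all 3 WT comparisons and tested in all 6, 445 and 625 changed the same way in all 3 Het comparisons, where 70.5 and 113 would be shared by independent draws, and 0 changed the opposite way. The genotypes share no library, so noise of shared control libraries cannot produce this overlap. All 6 comparisons were made against scramble cells, so an effect of the scramble sgRNA itself is not excluded. The 3 knockdowns of a genotype share scramble libraries, which may add to their overlap. Simulations without effects gave 0 but call few genes, so cannot size this part.

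Fold changes correlated across genes, which are not independent replicates. Over 10507 genes, r between the WT knockdowns was 0.904 for Eif4a3 and Magoh, 0.833 for Eif4a3 and Rbm8a and 0.791 for Magoh and Rbm8a, against 0.502, 0.497 and 0.500 simulated from the shared scramble libraries alone (covariances 0.127, 0.0712 and 0.0729 against 0.0147, 0.0144 and 0.0146). In Het cells r was 0.899, 0.884 and 0.903 against simulated values of 0.500, 0.499 and 0.500 (covariances 0.171, 0.148 and 0.137 against 0.0154, 0.0153 and 0.0153). Between genotypes, which share no libraries, r was 0.799 for Eif4a3, 0.757 for Magoh and 0.670 for Rbm8a, and 3229 of 3236, 3023 of 3030 and 1180 of 1182 genes called in both genotypes had the same direction.

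Known targets of NMD rose as a list in every knockdown, though not every member did. Besides Eif4a2 and Ddit3, the values of the authors' deposited table for the Eif4a3, Magoh and Rbm8a sgRNAs were 0.78, 0.81 and 0.50 for the translation-regulated Atf4 and 0.92, 1.17 and 0.76 for the RNA-binding Hnrnpdl in WT cells, and 0.63, 0.65 and 0.61 and 0.93, 0.98 and 0.88 in Het cells. The tumour suppressor gene Rassf1 rose by 1.42, 1.19 and 1.13 and the snoRNA host Gas5 had 0.18, 0.26 and 0.39 in Het cells in the authors' deposited table, while Srsf6 (-0.17, -0.16 and -0.15 in WT cells), whose poison-exon transcript NMD removes, did not. In the same order in WT cells, 16, 19 and 12 of 35 were called higher and 4, 2 and 1 lower (list p 1.42e-13, 4.14e-18 and 1.03e-10). Medians were 0.18, 0.23 and 0.07, with 17, 22 and 12 higher and 4, 2 and 3 lower adjusted over the list alone. In Het cells 21, 17 and 18 of 35 were called higher and 3, 1 and 0 lower (list p 9.20e-14, 2.05e-15 and 2.62e-16). Medians were 0.26, 0.26 and 0.21, with 22, 20 and 19 higher and 4, 2 and 0 lower adjusted over the list alone. The EJC and NMD protein list holds the targeted genes and was not called. Without the targeted genes, a test chosen after seeing the results and not run at 0.05, it was called higher in all but WT Rbm8a. List p was 0.0431 and 0.0307 in WT, 0.000809, 0.00956 and 0.0247 in Het. The NMD factor gene Upf2 had 0.55, 0.62 and 0.29 in WT and 0.69, 0.58 and 0.46 in Het cells and the EJC-associated Pnn 0.73, 0.46 and 0.45 in Het cells in the authors' deposited table. With the targets included in WT cells, 5, 6 and 2 of 22 were called higher and 2, 3 and 1 lower (list p 0.516, 0.573 and 0.317). Medians were 0.13, 0.12 and -0.01, with 5, 8 and 2 higher and 2, 3 and 2 lower adjusted over the list alone. In Het cells 13, 7 and 8 of 23 were called higher and 2, 1 and 1 lower (list p 0.0570, 0.325 and 0.334). Medians were 0.22, 0.16 and 0.18, with 14, 8 and 8 higher adjusted over the list alone. Splicing-factor genes went both ways, with the spliceosome scaffold Prpf8 at -0.40, -0.64 and -0.36 in WT and -0.53, -0.53 and -0.42 in Het cells, and Srsf9 at -0.41, -0.35 and -0.29 in WT cells in the authors' deposited table. Their list was called, lower, only in the WT Rbm8a comparison, and the Rbm8a effect on it differed between genotypes (list p 0.000196), while the sgRNAs were not tested against each other. In WT cells 3, 6 and 1 of 30 were called higher and 8, 5 and 7 lower (list p 0.516, 0.936 and 0.0178, at 0.05 0.122 for Rbm8a). Medians were 0.00, -0.02 and -0.10, with 9, 5 and 7 lower adjusted over the list alone. In Het cells 10, 5 and 6 of 30 were called higher and 8, 6 and 4 lower (list p 0.759, 0.589 and 0.656). Medians were 0.04, -0.03 and 0.02, with 8, 8 and 4 lower adjusted over the list alone.

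The ATF4 stress programme split. In the authors' deposited table the phosphatase-regulator gene Ppp1r15a had 0.997, 0.96 and 0.42 in WT and 1.63, 1.31 and 1.11 in Het cells and Atf3 1.32, 1.24 and 0.73 in WT cells, while the serine synthesis genes Phgdh (-0.73, -0.83 and -0.46 in WT, -0.96, -0.81 and -0.69 in Het cells) and Psat1 (-0.16, -0.28 and -0.09, -0.43, -0.18 and -0.21), which ATF4 induces, did not follow. In WT cells 13, 12 and 5 of 32, 32 and 30 were called higher and 8, 8 and 5 lower (list p 1.03e-04, 0.0180 and 0.453, at 0.05 0.111 for Magoh). Medians were 0.09, 0.05 and -0.03, with 14, 13 and 5 higher and 8, 9 and 6 lower adjusted over the list alone. In Het cells 11, 10 and 8 of 32, 32 and 31 were called higher and 11, 7 and 6 lower (list p 0.0213, 0.0173 and 0.0492, at 0.05 0.128 for Eif4a3, 0.128 for Magoh and 0.205 for Rbm8a). Medians were 0.12, 0.08 and 0.06, with 12, 10 and 10 higher and 11, 8 and 9 lower adjusted over the list alone. Genes induced by p53 rose in Het cells, as did Trp53inp1 by 1.33, 1.23 and 1.06, the TNF receptor family gene Eda2r by 0.97, 1.02 and 0.88 and the p53-degrading Mdm2 by 0.58, 0.41 and 0.38 in the authors' deposited table. The BH3-only gene Pmaip1 had 0.84, 0.81 and 0.49 in WT and 1.32, 1.13 and 0.96 in Het cells in the authors' deposited table, and the p53 target Ephx1 had -0.31, -0.39 and -0.13 in WT and -0.58, -0.39 and -0.32 in Het cells. For p53 targets in WT cells 9, 8 and 3 of 30, 30 and 28 were called higher and 6, 6 and 1 lower (list p 0.290, 0.452 and 0.453). Medians were 0.03, 0.04 and -0.03, with the same counts adjusted over the list alone. In Het cells 12, 15 and 11 of 30 were called higher and 3, 2 and 1 lower (list p 7.54e-04, 1.15e-05 and 1.91e-04). Medians were 0.31, 0.27 and 0.15, with 13, 15 and 12 higher and 5, 2 and 2 lower adjusted over the list alone. Pmaip1 also belongs to the list of BCL2 family and caspase genes, which was called in no comparison. In WT cells 1, 2 and 1 of 28, 28 and 26 were called higher and 5, 6 and 2 lower (list p 0.500, 0.485 and 0.701). Medians were -0.09, -0.04 and -0.02, with 4, 6 and 2 lower adjusted over the list alone. In Het cells 3, 3 and 2 of 28 were called higher and 10, 10 and 6 lower (list p 0.351, 0.476 and 0.608). Medians were -0.11, -0.10 and -0.05, with the same counts adjusted over the list alone.

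Lysosomal and ER genes rose. The lysosomal membrane gene Lamp1 rose by 0.62, 0.54 and 0.28 in WT and 0.71, 0.52 and 0.47 in Het cells, the proton pump gene Atp6v1h by 0.74, 0.67 and 0.40 in WT cells, the autophagosome gene Map1lc3b by 0.87, 0.75 and 0.60 and the folliculin partner Fnip1 by 0.71, 0.58 and 0.52 in Het cells in the authors' deposited table, against -0.41, -0.47 and -0.25 in WT cells for the cholesterol exporter gene Npc1. For the autophagy and lysosome list, 27, 25 and 17 of 51 were called higher and 1, 1 and 0 lower (list p 3.72e-12, 2.85e-08 and 6.08e-08) in WT cells. Medians were 0.25, 0.25 and 0.14, with 28, 26 and 21 higher and 1, 2 and 0 lower adjusted over the list alone. In Het cells 24, 22 and 20 of 51 were called higher and 3, 2 and 2 lower (list p 4.42e-07, 8.11e-06 and 4.00e-05). Medians were 0.21, 0.18 and 0.15, with 26, 22 and 21 higher and 4, 2 and 2 lower adjusted over the list alone. The ER chaperone gene Hspa5 rose by 0.49, 0.63 and 0.27 in WT and 0.64, 0.67 and 0.61 in Het cells, and its cochaperone gene Dnajb9 by 0.92, 0.94 and 0.44 and 1.52, 1.34 and 1.29, in the authors' deposited table. Within the ER list 13, 13 and 6 of 23 were called higher and 1, 0 and 0 lower (list p 1.77e-04, 6.49e-07 and 2.38e-04) in WT cells. Medians were 0.17, 0.22 and 0.09, with 14, 13 and 6 higher adjusted over the list alone. In Het cells 12, 14 and 14 of 24, 24 and 23 were called higher and 2, 1 and 0 lower (list p 5.57e-04, 8.11e-06 and 1.33e-05). Medians were 0.25, 0.27 and 0.21, with 12, 15 and 15 higher adjusted over the list alone. Cytosolic heat shock genes included falling members such as Hspa4 (-0.50, -0.55 and -0.53 in Het cells) beside Hspa1b (0.49, 0.55 and 0.37 in WT cells) and Dnajb1 (0.49, 0.42 and 0.34) in the authors' deposited table. For these 8, 8 and 4 of 17 were called higher and 2, 2 and 3 lower (list p 0.0179, 0.0158 and 0.0974, at 0.05 0.0854 for Eif4a3 and 0.0749 for Magoh) in WT cells. Medians were 0.20, 0.22 and 0.17, with 9, 11 and 7 higher and 2, 3 and 3 lower adjusted over the list alone. In Het cells 9, 8 and 8 of 18 were called higher and 2 each lower (list p 0.110, 0.0396 and 0.0265, at 0.05 0.131 for Magoh and 0.105 for Rbm8a). Medians were 0.17, 0.24 and 0.27, with 9 each higher adjusted over the list alone. Of mitochondrial chaperone and protease genes, Clpx had -0.49, -0.50 and -0.37 and Hspe1 -0.60, -0.47 and -0.43 in WT cells in the authors' deposited table. For that list 1, 0 and 0 of 21 were called higher and 6, 8 and 5 lower (list p 0.0519, 0.0154 and 0.0101, at 0.05 0.0749 for Magoh and 0.0747 for Rbm8a) in WT cells. Medians were -0.05, -0.13 and -0.13, with 6, 8 and 8 lower adjusted over the list alone. In Het cells 0, 1 and 0 of 21 were called higher and 8, 7 and 4 lower (list p 0.0139, 0.0842 and 0.123, at 0.05 0.0710 for Eif4a3). Medians were -0.16, -0.16 and -0.12, with 9, 9 and 4 lower adjusted over the list alone.

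Adhesion, matrix and lipid synthesis genes fell. In the authors' deposited table the actin crosslinker gene Flna (-1.02, -1.20 and -0.56 in WT, -1.41, -1.11 and -0.95 in Het cells), the integrin adaptor gene Tln1 (-0.82, -1.05 and -0.49 and -1.02, -0.99 and -0.78) and the integrin gene Itga3 (-0.87, -1.02 and -0.50 and -1.32, -1.36 and -1.06) fell. For the adhesion list 1, 1 and 0 of 62, 62 and 60 were called higher and 30, 35 and 17 lower (list p 1.73e-07, 3.61e-11 and 1.74e-05) in WT cells. Medians were -0.19, -0.25 and -0.13, with 1, 1 and 2 higher and 32, 36 and 22 lower adjusted over the list alone. In Het cells 2, 0 and 2 of 67, 63 and 62 were called higher and 34, 38 and 29 lower (list p 3.80e-14, 1.32e-18 and 7.13e-12). Medians were -0.29, -0.31 and -0.21, with 2 each higher and 34, 38 and 31 lower adjusted over the list alone. The collagen genes Col8a1 (-0.83, -0.82 and -0.42 in WT, -1.04, -1.14 and -0.74 in Het cells) and Col5a1 (-0.96, -0.85 and -0.33, -1.10, -0.81 and -0.73) fell wherever called in the authors' deposited table. In the matrix list 2, 2 and 1 of 45, 45 and 41 were called higher and 20, 25 and 7 lower (list p 4.14e-07, 7.91e-08 and 0.00662, at 0.05 0.0982 for Rbm8a) in WT cells. Medians were -0.30, -0.37 and -0.12, with 2, 3 and 1 higher and 22, 25 and 7 lower adjusted over the list alone. In Het cells 5, 2 and 3 of 49, 47 and 45 were called higher and 32, 31 and 23 lower (list p 2.91e-09, 7.12e-10 and 1.46e-06). Medians were -0.51, -0.45 and -0.33, with 5, 3 and 4 higher and 33, 32 and 29 lower adjusted over the list alone. Fatty acid and sterol enzyme genes had, in the authors' deposited table, -0.84, -1.03 and -0.55 and -1.26, -1.22 and -1.001 for Acaca, -0.70, -0.60 and -0.32 and -1.12, -1.001 and -0.75 for Sqle and -0.73, -0.73 and -0.66 for Fasn in Het cells. Among cholesterol and SREBP targets 3, 0 and 0 of 25 were called higher and 18, 14 and 5 lower (list p 5.32e-06, 9.90e-06 and 0.00245) in WT cells. Medians were -0.33, -0.27 and -0.12, with 3, 2 and 0 higher and 19, 19 and 7 lower adjusted over the list alone. In Het cells none of 25 were called higher and 21, 19 and 18 lower (list p 8.11e-16, 7.16e-15 and 4.89e-11). Medians were -0.54, -0.48 and -0.38, with 21, 21 and 19 lower adjusted over the list alone. The intermediate filament gene Vim had -0.47, -0.54 and -0.29 and -0.76, -0.86 and -0.53, and S100a4 -0.59, -0.56 and -0.29 and -1.07, -0.89 and -0.58, in the authors' deposited table, where the collagen gene Col1a1 had -0.92, -0.80 and -0.28 and -0.77, -0.79 and -0.61. For fibroblast markers none of 7 were called higher and 3, 4 and 2 lower (list p 0.0485, 0.0214 and 0.332, at 0.05 0.0992 for Eif4a3 and 0.0632 for Magoh) in WT cells. Medians were -0.20, -0.35 and -0.26, with the same counts adjusted over the list alone. In Het cells none of 8, 7 and 7 were called higher and 4, 5 and 3 lower (list p 5.01e-04, 1.99e-05 and 0.00226). Medians were -0.52, -0.79 and -0.53, with the same counts adjusted over the list alone.

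**Figure D2:**
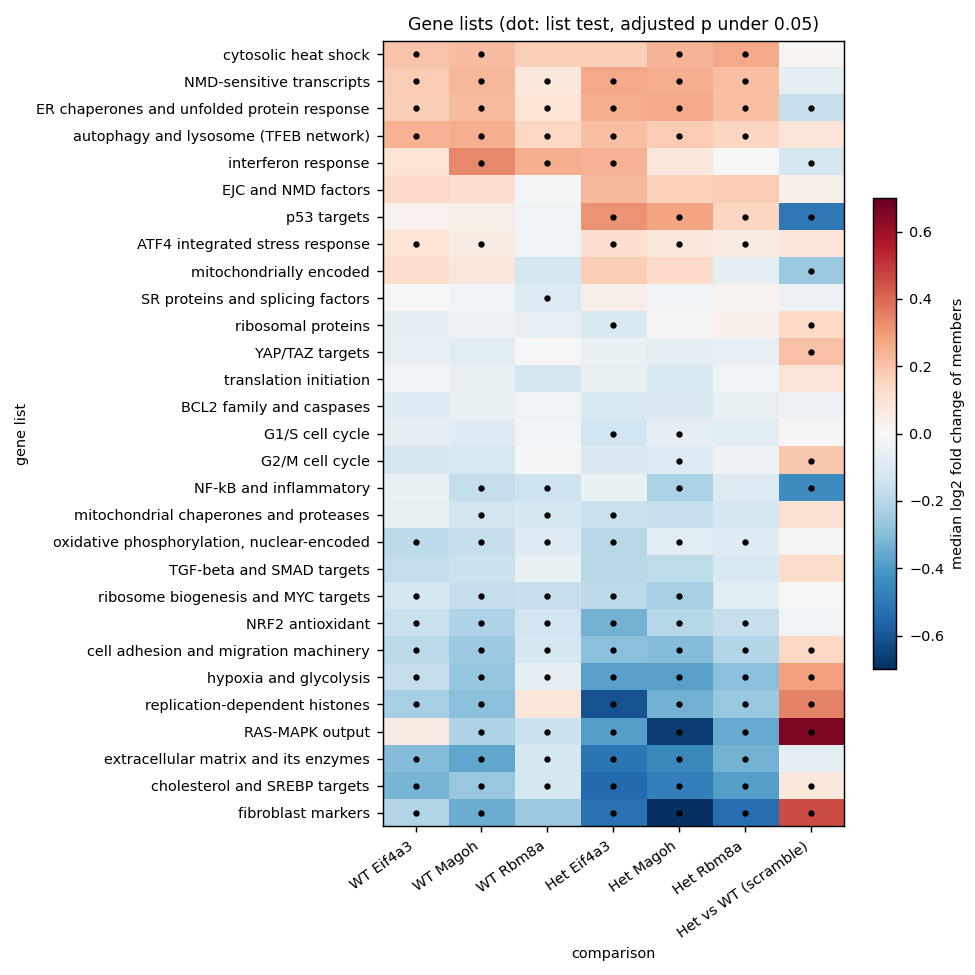
Median log2 fold change (colour) of 29 gene lists (rows) in the 6 knockdown comparisons and in Het against WT scramble cells (columns). Dots mark lists with an adjusted p below 0.05.

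Energy metabolism and antioxidant genes fell in part. In the authors' deposited table the complex I gene Ndufs1 had -0.92, -1.05 and -0.60 in WT and -1.11, -0.97 and -0.90 in Het cells and the complex II gene Sdha -0.81, -1.003 and -0.57 and -1.04, -1.11 and -0.85. For the nuclear-encoded oxidative phosphorylation list none of 44 were called higher and 21, 18 and 9 lower (list p 2.38e-06, 1.15e-05 and 8.21e-04) in WT cells. Medians were -0.18, -0.17 and -0.09, with 22, 18 and 10 lower adjusted over the list alone. In Het cells 1, 2 and 1 of 44 were called higher and 18, 12 and 10 lower (list p 5.24e-05, 0.00671 and 0.00289, at 0.05 0.107 for Magoh and 0.0681 for Rbm8a). Medians were -0.20, -0.08 and -0.09, with 20, 12 and 9 lower adjusted over the list alone. Mitochondrially encoded transcripts were not called as a list, with mt-Nd3 at 0.39, 0.19 and 0.33 in WT cells in the authors' deposited table. For them 1, 2 and 1 of 13 were called higher and 0, 1 and 0 lower (list p 0.306, 0.509 and 0.972) in WT cells. Medians were 0.12, 0.08 and -0.12, with none lower adjusted over the list alone. In Het cells none of 13 were called higher and 1, 1 and 0 lower (list p 0.568, 0.814 and 0.906). Medians were 0.17, 0.13 and -0.06, with the same counts adjusted over the list alone. The glycolytic genes Gpi1 (-0.53, -0.66 and -0.36 in WT, -0.83, -0.93 and -0.63 in Het cells) and Ldha (-0.28, -0.47 and -0.14, -0.77, -0.69 and -0.49) fell where called, while Ndrg1, which hypoxia also induces, had 0.82, 0.68 and 0.29 in WT cells in the authors' deposited table. In the hypoxia and glycolysis list 3, 3 and 1 of 26, 26 and 23 were called higher and 12, 14 and 7 lower (list p 0.0357, 1.75e-04 and 0.0350, at 0.05 0.158 for Eif4a3 and 0.139 for Rbm8a) in WT cells. Medians were -0.17, -0.27 and -0.07, with 3, 4 and 1 higher and 12, 15 and 7 lower adjusted over the list alone. In Het cells 3, 0 and 0 of 26 were called higher and 16, 15 and 14 lower (list p 1.69e-08, 1.19e-10 and 1.46e-06). Medians were -0.38, -0.38 and -0.29, with 3, 0 and 1 higher and 16, 15 and 15 lower adjusted over the list alone. Of NRF2 targets the exporter gene Abcc1 had -0.53, -0.71 and -0.33 and -0.90, -0.82 and -0.68 and the glutathione reductase gene Gsr -0.60, -0.62 and -0.42 and -0.72, -0.75 and -0.57 in the authors' deposited table. There 3, 2 and 1 of 24, 24 and 22 were called higher and 10, 13 and 5 lower (list p 0.0116, 0.0154 and 0.0187, at 0.05 0.0854 for Eif4a3, 0.0787 for Magoh and 0.107 for Rbm8a) in WT cells. Medians were -0.16, -0.22 and -0.13, with 10, 13 and 7 lower adjusted over the list alone. In Het cells 2, 0 and 2 of 24 were called higher and 13, 9 and 8 lower (list p 8.30e-05, 5.85e-04 and 0.0265, at 0.05 0.121 for Rbm8a). Medians were -0.33, -0.20 and -0.16, with 17, 9 and 9 lower adjusted over the list alone.

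Growth signalling and cell cycle genes fell in part. The growth factor gene Hbegf had -0.40, -0.57 and -0.37 in WT and -0.71, -0.79 and -0.66 in Het cells and the chromatin gene Hmga2 -0.65, -0.98 and -0.64 in Het cells, beside Fos and Ccnd1, in the authors' deposited table. For RAS-MAPK output genes 2, 0 and 0 of 25, 25 and 22 were called higher and 5, 8 and 6 lower (list p 0.500, 0.0176 and 0.00741, at 0.05 0.0906 for Magoh and 0.0675 for Rbm8a) in WT cells. Medians were 0.05, -0.22 and -0.15, with the same counts adjusted over the list alone. In Het cells none of 26, 26 and 25 were called higher and 11, 15 and 11 lower (list p 5.85e-05, 2.23e-10 and 6.33e-06). Medians were -0.38, -0.67 and -0.35, with the same counts adjusted over the list alone. The replication genes Pola1 (-0.74, -0.73 and -0.47 in WT, -0.78, -0.65 and -0.58 in Het cells) and Pole (-0.51, -0.61 and -0.27, -0.70, -0.59 and -0.58) fell where called, and Cdc6 had 0.50, 0.47 and 0.40 in WT cells in the authors' deposited table. For G1/S 10, 10 and 5 of 43 were called higher and 15, 14 and 6 lower (list p 0.149, 0.229 and 0.535) in WT cells. Medians were -0.07, -0.09 and -0.02, with 16, 16 and 6 lower adjusted over the list alone. In Het cells 6, 8 and 6 of 43 were called higher and 19, 14 and 10 lower (list p 9.95e-04, 0.0181 and 0.0599, at 0.05 0.131 for Magoh). Medians were -0.14, -0.06 and -0.07, with 7, 9 and 7 higher and 20, 16 and 13 lower adjusted over the list alone. The spindle motor gene Kif11 had -0.77, -0.84 and -0.64 and -0.70, -0.71 and -0.68, the topoisomerase gene Top2a -0.49, -0.60 and -0.41 and -0.49, -0.54 and -0.53 and the kinetochore gene Ndc80 0.56, 0.66 and 0.32 and 0.63, 0.55 and 0.46 in the authors' deposited table. For the G2/M list 8, 7 and 4 of 35 were called higher and 11, 11 and 6 lower (list p 0.0949, 0.176 and 0.317) in WT cells. Medians were -0.11, -0.11 and -0.01, with 8, 7 and 7 higher and 11, 13 and 7 lower adjusted over the list alone. In Het cells 7, 7 and 6 of 35 were called higher and 11, 14 and 8 lower (list p 0.0773, 0.0238 and 0.334, at 0.05 0.131 for Magoh). Medians were -0.10, -0.09 and -0.04, with 8 each higher adjusted over the list alone. The linker histone gene Hist1h1d had -0.70, -0.74 and -0.27 and -1.001, -0.77 and -0.60, Hist1h4i 0.75, 0.37 and 0.42 and 0.62, 0.65 and 0.71, and Hist1h1c -0.45, -0.52 and -0.13 and -0.61, -0.46 and -0.34 in the authors' deposited table. Of replication-dependent histone genes 1 each of 24 were called higher and 10, 11 and 2 lower (list p 0.00107, 5.10e-04 and 0.496) in WT cells. Medians were -0.23, -0.29 and 0.08, with 10, 13 and 2 lower adjusted over the list alone. In Het cells 1, 2 and 2 of 25 were called higher and 22, 13 and 11 lower (list p 4.01e-11, 9.44e-04 and 0.00390, at 0.05 0.0508 for Rbm8a). Medians were -0.61, -0.34 and -0.27, with the same counts adjusted over the list alone.

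Genes of ribosome production fell in part. The pyrimidine synthesis gene Cad had -0.84, -1.02 and -0.46 in WT and -1.13, -0.73 and -0.76 in Het cells and the ribosome assembly gene Utp20 -0.35, -0.51 and -0.38 and -0.40, -0.47 and -0.42, while Nop14, another assembly gene, had 0.43, 0.57 and 0.06 and 0.72, 0.44 and 0.51 in the authors' deposited table. For ribosome biogenesis and MYC targets 2, 2 and 1 of 38 were called higher and 15, 16 and 17 lower (list p 0.0116, 0.00294 and 8.76e-07, at 0.05 0.114 for Eif4a3 and 0.0632 for Magoh) in WT cells. Medians were -0.12, -0.17 and -0.16, with 16, 17 and 20 lower adjusted over the list alone. In Het cells 2, 3 and 3 of 38 were called higher and 18, 20 and 10 lower (list p 8.22e-04, 3.32e-04 and 0.115). Medians were -0.18, -0.23 and -0.08, with 18, 22 and 12 lower adjusted over the list alone. Ribosomal protein genes moved little, with Rps12 at 0.50, 0.73 and 0.45 and 0.56, 0.91 and 0.79 and Rpl30 at -0.30, -0.46 and -0.23 and -0.65, -0.49 and -0.37 in the authors' deposited table. For these 2, 6 and 1 of 77 were called higher and 21, 14 and 7 lower (list p 0.0546, 0.498 and 0.198) in WT cells. Medians were -0.06, -0.04 and -0.06, with 19, 14 and 7 lower adjusted over the list alone. In Het cells 5, 8 and 11 of 77 were called higher and 25, 7 and 4 lower (list p 0.0287, 0.741 and 0.334, at 0.05 0.222 for Eif4a3). Medians were -0.10, 0.01 and 0.04, with 5, 8 and 6 higher and 25, 6 and 2 lower adjusted over the list alone. In the translation initiation list Eif4h had -0.31, -0.40 and -0.16 and -0.50, -0.29 and -0.36 and Cyfip1 -0.29, -0.43 and -0.18 and -0.47, -0.40 and -0.30, against the rise of Eif4a2, in the authors' deposited table. There 4, 5 and 1 of 35 were called higher and 9, 10 and 11 lower (list p 0.811, 0.992 and 0.0702) in WT cells. Medians were -0.02, -0.05 and -0.12, with 9, 10 and 13 lower adjusted over the list alone. In Het cells 5, 4 and 5 of 35 were called higher and 11, 13 and 6 lower (list p 0.890, 0.388 and 0.704). Medians were -0.05, -0.10 and -0.03, with 6, 4 and 5 higher and 12, 14 and 7 lower adjusted over the list alone.

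Interferon and inflammatory genes split. Cxcl10 rose by 1.27, 1.42 and 0.74 in WT and Mx2 by 1.68, 1.94 and 1.39 in Het cells, whereas the cytokine gene Csf1 had -0.64, -0.69 and -0.19 and -0.91, -0.93 and -0.57 and the adhesion molecule gene Vcam1 -0.76, -0.73 and -0.43 and -0.75, -0.81 and -0.55 in the authors' deposited table. For the interferon list 11, 14 and 7 of 32, 32 and 30 were called higher and 4, 2 and 0 lower (list p 0.138, 0.00271 and 3.74e-04, at 0.05 0.0558 for Magoh) in WT cells. Medians were 0.09, 0.34 and 0.25, with 12, 14 and 9 higher and 4, 3 and 0 lower adjusted over the list alone. In Het cells 12, 9 and 7 of 34, 32 and 32 were called higher and 5, 8 and 4 lower (list p 0.0449, 0.301 and 0.612, at 0.05 0.190 for Eif4a3). Medians were 0.24, 0.08 and -0.00, with 6, 8 and 4 lower adjusted over the list alone. For the NF-kB list 2, 1 and 0 of 20, 20 and 18 were called higher and 5, 6 and 4 lower (list p 0.124, 0.0154 and 0.0421, at 0.05 0.0749 for Magoh and 0.139 for Rbm8a) in WT cells. Medians were -0.05, -0.16 and -0.15, with 5, 6 and 6 lower adjusted over the list alone. In Het cells 1, 2 and 2 of 21, 20 and 19 were called higher and 6 each lower (list p 0.134, 0.0396 and 0.220, at 0.05 0.131 for Magoh). Medians were -0.05, -0.22 and -0.09, with 1, 3 and 2 higher and 6, 7 and 7 lower adjusted over the list alone. In Het cells Il6 had 2.79, 2.60 and 2.27 in the authors' deposited table. The YAP/TAZ target Myof had -0.56, -0.66 and -0.37 and -0.85, -0.87 and -0.61 and the TGF-beta binding Ltbp1 -0.34, -0.40 and -0.17 and -0.54, -0.49 and -0.33 in the authors' deposited table. For YAP/TAZ targets 3 each of 22, 22 and 20 were called higher and 5, 4 and 3 lower (list p 0.459, 0.184 and 0.929) in WT cells. Medians were -0.06, -0.07 and 0.00, with the same counts adjusted over the list alone. In Het cells 4, 2 and 3 of 22 were called higher and 5, 5 and 3 lower (list p 0.221, 0.0842 and 0.334). Medians were -0.05, -0.07 and -0.06, with the same counts adjusted over the list alone. For TGF-beta and SMAD targets none of 23, 23 and 20 were called higher and 3, 4 and 1 lower (list p 0.422, 0.426 and 0.921) in WT cells. Medians were -0.17, -0.15 and -0.05, with 3, 4 and 0 lower adjusted over the list alone. In Het cells 2, 0 and 1 of 25, 25 and 24 were called higher and 8, 7 and 3 lower (list p 0.183, 0.129 and 0.479). Medians were -0.20, -0.18 and -0.11, with 9, 7 and 2 lower adjusted over the list alone.

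Few markers of other tissues were measured. The troponin gene Tnnt2 had 0.36, 0.36 and -0.00 in WT cells and 0.78, 0.58 and 0.39 in Het cells and the neural adhesion gene Ncam1 -0.42, -0.22 and -0.00 and -0.43, -0.52 and -0.26 in the authors' deposited table. Among muscle markers 1, 2 and 0 of 5, 5 and 2 were called higher and none lower (list p 0.471, 0.256 and 0.701) in WT cells. Medians were 0.21, 0.36 and 0.11, with the same counts adjusted over the list alone. In Het cells 3, 1 and 2 of 5, 4 and 3 were called higher and none lower (list p 0.0371, 0.0909 and 0.0968, at 0.05 0.0668 for Eif4a3). Medians were 0.78, 0.58 and 0.61, with 3, 1 and 3 higher adjusted over the list alone. For epithelial markers with the Eif4a3 and Magoh sgRNAs in WT cells, 3 and 2 of 5 were called higher and none lower (list p 0.00576 and 0.0475, at 0.05 0.0787 for Magoh). Medians were 0.75 and 0.50, with the same counts adjusted over the list alone. In each of the other 4 knockdowns a single gene of that list was called, and those results are left out. Immune, endothelial, neural and glial, and chondrocyte and adipocyte markers were called as lists in no knockdown, the lowest list p being 0.471, 0.525, 0.325 and 0.767. None of them had more than 1 gene higher and 1 lower in a knockdown, with the same counts adjusted over the list alone. In some lists that were not called the signs of median, mean and test differed. With the Eif4a3 sgRNA in WT cells these were RAS-MAPK output (median 0.05, mean -0.10), splicing factors, translation initiation and endothelial markers, and with the Rbm8a sgRNA there ATF4 targets (median -0.03, mean 0.04), p53 targets, YAP/TAZ targets and mitochondrially encoded and immune genes. With the Magoh sgRNA they were splicing factors, translation initiation, immune and neural markers in WT cells and chondrocyte markers in Het cells, and in Het cells also neural markers (Eif4a3) and translation initiation and interferon genes (Rbm8a).

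Among genes with many exons, more fell than rose. Among genes with 25 exons or more, 390, 429 and 263 were called lower and 74, 73 and 8 higher of 864 in WT cells with the Eif4a3, Magoh and Rbm8a sgRNAs, with medians of -0.19, -0.22 and -0.15. In Het cells 419, 450 and 406 of 845 genes with 25 exons or more were called lower and 99, 61 and 53 higher. There the medians were -0.23, -0.27 and -0.22. Psme4, Prpf8, Flna, Tln1, Acaca and Myof, named above, are such genes. Genes with 1 exon had medians of 0.07, 0.06 and 0.08 in WT and -0.00, 0.06 and 0.03 in Het cells. Between the Het and WT scramble cells the medians were 0.12 for 1 exon and 0.06 for 25 exons or more, where 141 genes were called higher and 64 lower of 846. The grouping by exon number was chosen after the fold changes had been seen.

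**Figure D3:**
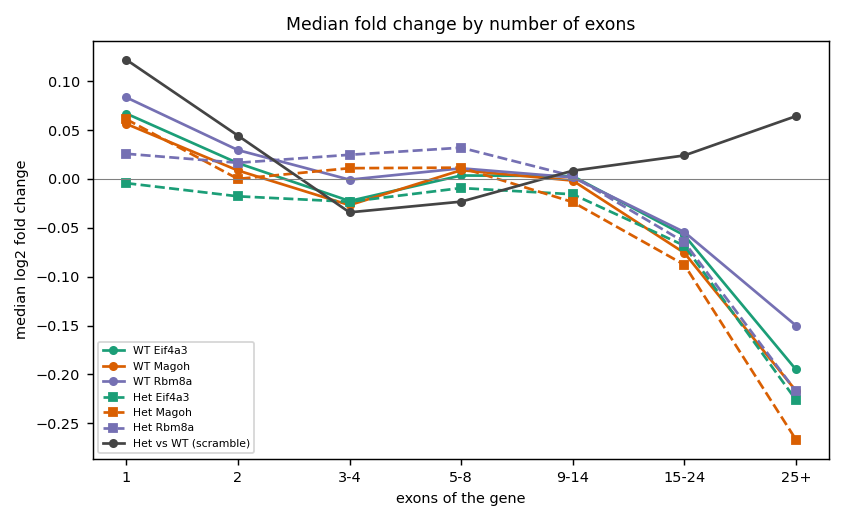
Median log2 fold change (y axis) of genes grouped by annotated number of exons (x axis) in the 7 comparisons (colours).

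Before knockdown, the Het scramble cells differed from the WT scramble cells in growth, p53 and lineage genes. In the authors' deposited table Ccnd1 was higher by 1.004 ± 0.09, Bgn by 1.86 ± 0.13, Ppl by 2.42 ± 0.19 and Eya2 by 2.13 ± 0.41, and Ddit3 was at -0.58 ± 0.16, Cxcl10 at -1.13 ± 0.23 and the p53 target Perp at -2.73 ± 0.29. Large values in the authors' deposited table included the pore-forming Gsdmd (8.91 ± 1.36), Ccdc7a (7.81 ± 1.23), Tmem47 (7.78 ± 0.51), Tram1l1 (6.13 ± 0.79), Hhipl1 (3.65 ± 0.48), Renbp (3.62 ± 0.38), the phosphodiesterase gene Pde8a (3.50 ± 0.51) and Rnf39 (3.17 ± 0.51). On the low side stood, in the authors' deposited table, Rps4l (-8.56 ± 1.05), the semaphorin gene Sema3e (-7.92 ± 1.19), Asb4 (-7.83 ± 1.26), Bicc1 (-7.77 ± 1.60), Zfp518b (-6.56 ± 0.94), Pde3b (-6.54 ± 0.53), Zfp979 (-5.74 ± 0.28) and Zfp37 (-5.59 ± 0.45). Of 14972 genes tested, 1168 were called higher and 1069 lower, and 586 differed at least 2-fold. The labels do not say how many lines each genotype had, so these differences cannot be ascribed to the Eif4e copy.

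Among p53 targets in this comparison, Eda2r (-1.002 ± 0.12), Trp53inp1 (-1.27 ± 0.15) and Mdm2 (-0.59 ± 0.09) were lower in the authors' deposited table, and none of 30 were called higher and 14 lower (list p 2.75e-11). The median was -0.50, with 15 lower adjusted over the list alone. RAS-MAPK output was higher, with Hmga2 at 1.29 ± 0.12 and Hbegf at 0.82 ± 0.12 in the authors' deposited table, and 13 of 26 were called higher and 1 lower (list p 4.29e-08). The median was 0.65, with 15 higher adjusted over the list alone. The glycolytic Aldoa (0.72 ± 0.08) and Ldha (0.70 ± 0.08), the mitotic Kif20a (0.87 ± 0.08) and Ccnb2 (1.05 ± 0.13) and the ribosomal Rpl17 (0.85 ± 0.07) and Rps14 (1.13 ± 0.12) were higher in the authors' deposited table. For hypoxia and glycolysis 12 of 27 were called higher and 1 lower (list p 1.41e-08). The median was 0.28, with 16 higher adjusted over the list alone. For G2/M 14 of 35 were called higher and none lower (list p 2.74e-09). The median was 0.19, with 16 higher adjusted over the list alone. For ribosomal proteins 24 of 77 were called higher and 2 lower (list p 3.43e-06). The median was 0.14, with 31 higher adjusted over the list alone. For adhesion 20 of 63 were called higher and 7 lower (list p 2.85e-05). The median was 0.14, with 21 higher and 8 lower adjusted over the list alone. The semaphorin Sema3a was at 0.84 ± 0.09 and the integrin Itgb7 at 1.72 ± 0.18 in the authors' deposited table. For histones 9 of 25 were called higher and 2 lower (list p 0.00118). The median was 0.35, with 14 higher adjusted over the list alone. For cholesterol targets 7 of 25 were called higher and none lower (list p 0.0207, at 0.05 0.118). The median was 0.08, with 9 higher and 1 lower adjusted over the list alone. The sterol demethylase gene Cyp51 was at 0.80 ± 0.09 in the authors' deposited table. The interferon-regulated H2-K1 (-0.91 ± 0.12), Isg15 (-1.37 ± 0.20) and the chemokine Cxcl1 (-0.93 ± 0.14) were lower in the authors' deposited table. For interferon genes none of 33 were called higher and 7 lower (list p 0.0173, at 0.05 0.119). The median was -0.12, with 8 lower adjusted over the list alone. For NF-kB genes 1 of 20 was called higher and 6 lower (list p 0.00435). The median was -0.44, with 2 higher and 9 lower adjusted over the list alone. For ER genes 1 of 23 was called higher and 4 lower (list p 0.0399, at 0.05 0.157). The median was -0.16, with 2 higher and 8 lower adjusted over the list alone. For mitochondrially encoded transcripts none of 13 were called higher and 6 lower (list p 0.0106). The median was -0.26, with the same counts adjusted over the list alone. For YAP/TAZ targets 8 of 22 were called higher and 1 lower (list p 0.0104, at 0.05 0.0602). The median was 0.21, with 9 higher adjusted over the list alone.

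Fibroblast and muscle genes also differed, with Vim at 0.77 ± 0.08, Prrx1 at 2.04 ± 0.25 and Tnnt2 at -0.66 ± 0.12 in the authors' deposited table. For fibroblast markers 4 of 8 were called higher and 1 lower (list p 0.00915). The median was 0.45, with the same counts adjusted over the list alone. For muscle markers none of 5 were called higher and 2 lower (list p 0.0173). The median was -1.10, with 3 lower adjusted over the list alone. For immune markers 1 of 4 was called higher and 2 lower (list p 0.0323, at 0.05 0.0579). The median was -1.32, with the same counts adjusted over the list alone. NMD-sensitive transcripts were not called as a list, although Gas5 was at -0.57 ± 0.08 in the authors' deposited table. Of them 2 of 35 were called higher and 6 lower (list p 0.101). The median was -0.07, with 7 lower adjusted over the list alone. The ATF4 targets, with Psat1 at 0.48 ± 0.07 in the authors' deposited table, were not called either, and 4 of 32 were called higher and 6 lower (list p 0.796). The median was 0.09, with 6 higher and 8 lower adjusted over the list alone. Nor were the lists not yet named in this comparison. Signs of median, mean and test differed for ATF4 targets (mean -0.06), ribosome biogenesis, G1/S and heat shock, none of them called.

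The difference was uneven over chromosomes. Genes of chromosome 18, such as Rps14 and Rpl17, were higher in Het cells, with a median of 0.62 over 261 genes, 202 called higher of 203 called, and 93.1% positive. The first, middle and last parts of its gene order had medians of 0.63, 0.62 and 0.63, and Het minus WT medians of 0.61, 0.58, 0.53 and 0.58 were found in the scramble, Eif4a3, Magoh and Rbm8a libraries. Chromosome 12 had a median of 0.25 over 379 genes (124 of 134 called genes higher), falling from 0.47 and 0.35 in its first parts to -0.09 in its last. Chromosome 1 had a median of -0.16 (99 of 114 called genes lower) and chromosome 14 of -0.15 (60 of 68 lower).

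**Figure D4:**
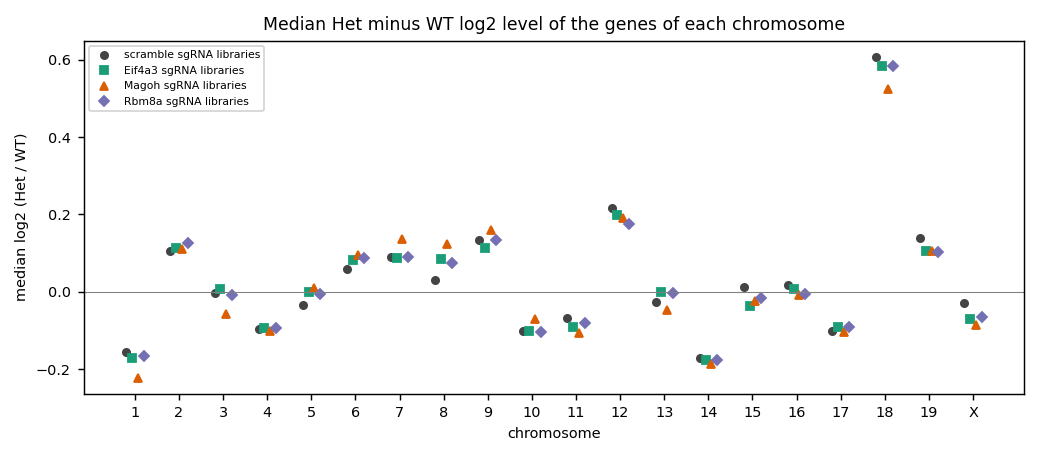
Median Het minus WT log2 level (y axis) of the genes of each chromosome (x axis). Points are the medians in the scramble, Eif4a3, Magoh and Rbm8a sgRNA libraries.

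Some knockdown effects differed between genotypes when the difference itself was tested. With the Eif4a3 sgRNA the kinesin gene Kif5c had -0.11 ± 0.19 in WT and 1.05 ± 0.22 in Het cells in the authors' deposited table, and Ccnd1 had -0.96 in WT and -1.80 in Het cells. Of 19165 genes, 159 differed, 55 with a more positive and 104 with a more negative Het effect. In 99 of them the effects had the same sign and were larger in Het cells, in 3 larger in WT cells, and in 57 the signs were opposite. Eif4a3 itself fell further in Het cells, by a called difference of -0.38, so that deeper silencing is not set apart from genotype here. The histone gene Hist1h4h had 0.01 ± 0.17 in WT and -1.56 ± 0.16 in Het cells in the authors' deposited table, and Lonrf3 had 0.89 ± 0.19 and -0.27 ± 0.15. With the Magoh sgRNA, Lonrf3 had 0.76 ± 0.19 and -0.90 ± 0.16, Perp -0.12 ± 0.07 and 0.73 ± 0.13 and Ppl -0.82 ± 0.24 and -2.20 ± 0.20 in the authors' deposited table. Here 94 genes differed, 22 more positive and 72 more negative in Het cells. With the Rbm8a sgRNA, Dnajb9 had 0.44 ± 0.15 and 1.29 ± 0.16, Rora 0.72 ± 0.14 and 1.48 ± 0.16, Pvt1 0.79 ± 0.11 and 1.54 ± 0.13, Tspo -0.33 ± 0.18 and -1.35 ± 0.17, and Mov10 -0.38 ± 0.16 and -1.26 ± 0.18 in the authors' deposited table. There 157 genes differed, 96 more positive and 61 more negative, and in 114 of them the effects had the same sign and were larger in Het cells. The 3 tests share all 6 scramble libraries, so that a gene set apart in the scramble libraries of the genotypes, such as Perp or Ppl, enters each of them.

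**Figure D5:**
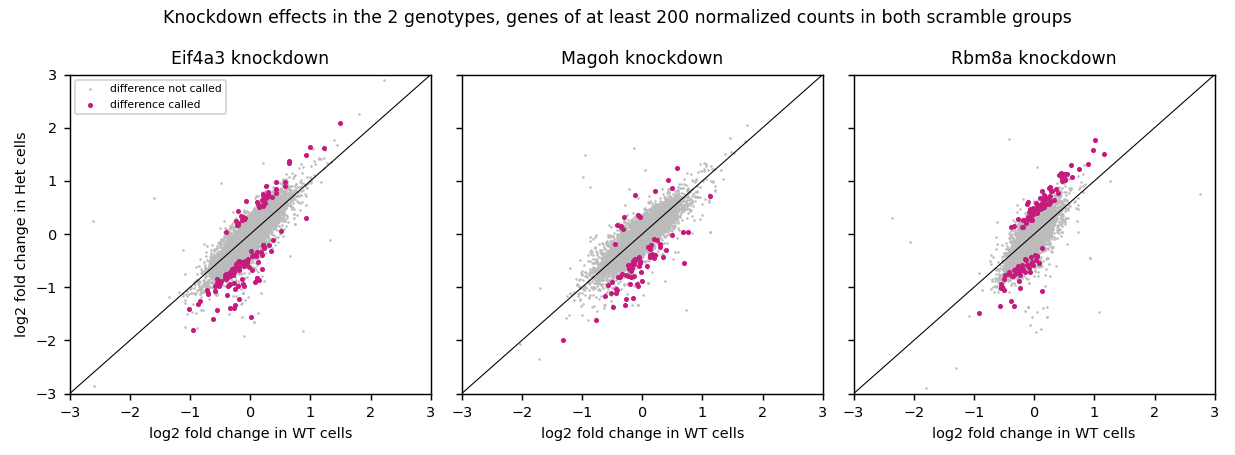
Log2 fold change in Het cells (y axis) against WT cells (x axis) for each sgRNA, each point a gene with at least 200 normalized counts in both scramble groups. Magenta points are genes whose effects differed between genotypes.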

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

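The genes and lists below stood out because the effect of a knockdown differed between WT and Het cells in a test of that difference itself, and the 3 patterns after them, with part of their tests, were chosen after the results had been seen. Values are Het minus WT differences of log2 fold change, positive where the Het effect was more positive. With the Eif4a3, Magoh and Rbm8a sgRNAs 159, 94 and 157 genes differed.

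With the Eif4a3 sgRNA the named genes with a more positive Het effect were Kif5c 1.16, Zfp976 1.02, Snapc5 1.01, Cela1 0.81, Atp6v1f 0.70, Trp53inp1 0.69, Perp 0.64, Ppp1r15a 0.63, Eda2r 0.55, Pnn 0.51, Rpl13 0.39, Magoh 0.37, Snrnp70 0.37 and Mdm2 0.33. More negative in Het cells were Hist1h4h -1.57, Lonrf3 -1.16, Hist1h4b -1.12, Itgb7 -1.09, Hist4h4 -1.06, Prrx1 -0.94, Hist2h4 -0.86, Hmga2 -0.85, Ccnd1 -0.84, Hist1h2bj -0.81, Dusp6 -0.79, Ftl1 -0.67, Bgn -0.66, Gpnmb -0.63, Ier3 -0.59, Ldha -0.49, Pfkp -0.46, Itga3 -0.45, Aldoa -0.44, Met -0.42, Sqle -0.42, Acaca -0.42, G6pdx -0.40, Flna -0.40, Eif4a3 -0.38, Cav1 -0.38 and Abcc1 -0.36. As lists, more positive medians were those of muscle markers 0.60, p53 targets 0.26, NMD-sensitive transcripts 0.081 and EJC and NMD factors 0.067, and more negative ones those of RAS-MAPK output -0.43, histones -0.41, cholesterol synthesis -0.31, hypoxia and glycolysis -0.23, extracellular matrix -0.16, adhesion -0.12, NRF2 antioxidant -0.12, fibroblast markers -0.076 and G1/S cell cycle -0.061. For fibroblast markers the mean, 0.06, had the opposite sign to the median and the test (adjusted p 0.0118).

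With the Magoh sgRNA the effect was more positive in Het cells for Kif5c 1.16, Tbc1d8 1.04, Tsnax 0.88, Perp 0.85, Cyb561d2 0.75, Trp53inp1 0.65, Eda2r 0.60 and Rpl13 0.42. It was more negative for Lonrf3 -1.67, Ppl -1.37, Trim30a -1.23, Ms4a4d -1.08, Fam213a -1.05, Hmga2 -0.90, Itgb7 -0.84, Ier3 -0.75, Gpnmb -0.73, Ccnd1 -0.69, Ndrg1 -0.63, B2m -0.51, G6pdx -0.46, Pfkp -0.45 and Met -0.39. List medians were more positive for p53 targets 0.29 and oxidative phosphorylation 0.073, and more negative for RAS-MAPK output -0.41, cholesterol synthesis -0.28, interferon response -0.28, hypoxia and glycolysis -0.12, NRF2 antioxidant -0.11 and adhesion -0.061.

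With the Rbm8a sgRNA the genes Dnajb9 0.84, Rora 0.76, Pvt1 0.75, Bloc1s2 0.72, Gpatch3 0.70, Ppp1r15a 0.70, Perp 0.69, Cdkn1a 0.65, Rassf1 0.64, Eda2r 0.62, Trp53inp1 0.60, Snhg15 0.60, Pnn 0.50, Snrnp70 0.45, Rpl13 0.45, Nop14 0.45, Magoh 0.40, Eif4a2 0.35, Hspa5 0.35 and Gas5 0.34 had a more positive Het effect. The genes Hist1h4h -1.21, Ppl -1.17, Tspo -1.02, Ms4a4d -1.02, Mov10 -0.88, Hist1h2bj -0.63, Itga3 -0.56, Ccnd1 -0.56, Acaca -0.45, Cav1 -0.44, Sqle -0.43, Flna -0.39, Met -0.37, Aldoa -0.37, Ldha -0.35 and Abcc1 -0.35 had a more negative one. List medians were more positive for p53 targets 0.21, NMD-sensitive transcripts 0.17, ER chaperones 0.12, ATF4 targets 0.11, ribosome biogenesis 0.11, EJC and NMD factors 0.10, translation initiation 0.086, splicing factors 0.066, ribosomal proteins 0.064 and heat shock 0.056. They were more negative for histones -0.29, cholesterol synthesis -0.26, fibroblast markers -0.25, RAS-MAPK output -0.23, interferon response -0.20, extracellular matrix -0.17, adhesion -0.15, hypoxia and glycolysis -0.13 and G1/S cell cycle -0.051, the mean of the fibroblast markers being 0.04 where the test was downward (adjusted p 0.00554). In the Het against WT scramble comparison, whose libraries enter all 3 tests, the called medians of p53 targets (-0.50), RAS-MAPK output (0.65), cholesterol synthesis (0.08), hypoxia (0.28), adhesion (0.14), histones (0.35), fibroblast (0.45) and muscle markers (-1.10) and ER chaperones (-0.16) ran the other way. So did those of NMD-sensitive transcripts, splicing factors, ribosome biogenesis and G1/S, not called there. The called medians of interferon genes (-0.12) and ribosomal proteins (0.14) ran the same way, as did the uncalled ones of the other lists. With a preset correlation of 0.05 the calls of NMD-sensitive transcripts (0.166) and EJC and NMD factors (0.156) with Eif4a3, oxidative phosphorylation (0.146) and NRF2 (0.207) with Magoh and G1/S (0.183) and heat shock (0.0920) with Rbm8a were lost (list p there in brackets).

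Chromosome 18 genes were higher in Het than in WT cells. A few strong genes do not account for it, since 93.1% of its genes had a positive difference, nor do the scramble libraries alone, since the lowest median shift in the knockdown libraries was 0.526, nor level, GC content or length of the genes, after whose removal the shift was 0.630. The medians of the first, middle and last parts of the chromosome differed by only 0.00865, which is consistent with a gain of the whole chromosome in the Het cells or its loss in the WT cells. The shift of 0.624 could belong to the Eif4e copy or to a difference between lines, as the labels give no number of lines. Karyotyping would test the gain or loss, but not its cause.

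More genes with many exons fell than rose. Transcript length and genomic span do not explain the fall with exon number (1.32 and 1.34 times the slope with them in the fit). Nor do GC content and level (0.911 times) or intronless and noncoding genes (1.298 times without them). WT scramble libraries alone do not (Het slope nearest to 0 at -9.72 standard errors over genes), but trends in both scramble groups might. Between scramble cells of the genotypes the slope was -0.00306, or -0.0127 with GC content and level in the fit. It was 0.0154 in protein-coding genes with at least 2 exons, so it changed sign with the model. Loss of EJC deposition on spliced RNA is a hypothesis. Without junction reads, splicing is not separated from later steps.

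The Rbm8a sgRNA changed genes less in WT than in Het cells. Weaker silencing does not account for it, since the Rbm8a falls of the genotypes differed by a z of only 0.696, and lower precision does not either, since with the errors removed the spread of effects in WT was still 0.536 times that in Het cells. For Eif4a3 and Magoh, measured against the same scramble libraries, the ratios of WT to Het spread were 0.736 and 0.904. The lower of them exceeded that of Rbm8a by 0.200. This does not exclude a part of the scramble libraries of either genotype, as a shift they share need not lower the ratios equally. The spread in Het cells was 1.87 times that in WT cells, and a dependence on Eif4e dose cannot be told apart from other differences between the cells. Protein levels of Y14 were not analysed here.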

How the results depend on the processing

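No paired analysis was possible because the deposited tables hold no value per library. For the same reason several alternatives set before the data were examined were not run: leave-one-out fits, replicate number as a block, TMM or other size factors, other tests of counts, another pseudocount, 1 fit of all libraries and an estimated correlation between the genes of a list. The filters on level had been planned, whereas centring, the restriction to genes tested in all 7 tables, centring by chromosome, the preset correlation of 0.05, lists without the targeted genes and removal of the exon trend were chosen after the tables had been seen. All 55 alternative counts, of changed genes and of called lists, stayed within 1.5 times the main count: without any filter the knockdowns gave 4084, 4328 and 1250 genes in WT and 5350, 4442 and 3446 in Het cells, a mean of at least 50 gave 212, 117 and 219 genes that differed between genotypes with the Eif4a3, Magoh and Rbm8a sgRNAs, and centring by chromosome gave 1722 genes (761 higher and 961 lower) for Het against WT scramble. Centring turned a majority of lower genes into one of higher genes: 2265 higher and 2117 lower with Eif4a3 and 2457 and 2190 with Magoh in WT, and 2937 and 2548, 2441 and 2218, and 1912 and 1840 with Eif4a3, Magoh and Rbm8a in Het cells, where 1628 and 1470 changed with all 3. Of 161 called lists, all 161 held without the targeted genes, where 6 more were called, and 111 held with a correlation of 0.05 and 143 with a mean of at least 50, where 2 more were called. Of 121 lists called in the comparisons that were centred, 118 held after centring and 113 after removal of the exon trend, and of 16 called between the scramble cells all 16 held after centring by chromosome. Of the named values, 876 kept direction and call without a filter and 11 lost the call, and 882 kept them after centring while 5 lost the call. Centring by chromosome left 113 named Het and WT differences as they were, 21 lost the call and 2 reversed: Eif1a, at -0.000470898, and Stard4, on chromosome 18, at -0.0334, by construction, as the median of their chromosome was subtracted. Depth limits low-count genes most: Magohb, Olfr461, mt-Co2 and Hist2h2aa2 rest on few reads in at least 1 group.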

Other observations

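The tests in this part were chosen after the results had been seen. Genes annotated as long intergenic noncoding RNA rose more often than they fell with every sgRNA. Of 150 such genes in WT cells 34, 37 and 17 were called higher and 8, 6 and 4 lower with the Eif4a3, Magoh and Rbm8a sgRNAs, and of 119 in Het cells 38, 33 and 31 were called higher and 14, 7 and 11 lower. Pvt1, which lies next to Myc, had 1.26, 1.37 and 0.79 in WT and 1.67, 1.74 and 1.54 in Het cells in the authors' deposited table. Host genes of small nucleolar RNAs, whose spliced transcripts carry little coding sequence, had medians of 0.20, 0.28 and 0.07 in WT and 0.46, 0.41 and 0.55 in Het cells over 12 genes. Of these 12 genes 6, 7 and 4 were called higher in WT and 8, 7 and 9 in Het cells. With Eif4a3 2 were called lower in WT and 1 in Het cells. Protein-coding genes with an annotated NMD transcript had medians of -0.02, -0.02 and -0.01 in WT cells, beside -0.03, -0.04 and -0.02 for those without. In Het cells the medians were -0.02, -0.02 and -0.00 with and -0.05, -0.05 and -0.02 without.

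The knockdowns were also set against each other within a genotype, which leaves out the scramble libraries. Eif4a3 and Magoh differed in 50 of 11101 genes in WT and 302 of 10584 in Het cells, Eif4a3 and Rbm8a in 1113 and 488, and Magoh and Rbm8a in 1657 and 78. The error of these differences is approximate. The 7 measured genes of the Y chromosome had a median of 1.02 between the Het and WT scramble cells, 4 of them called higher. Across genes, the Het against WT scramble values had covariances of 0.00697, -0.00136 and 0.00499 with the WT knockdown effects (r 0.0506, -0.00915 and 0.0550), where shared scramble libraries alone gave 0.0145, 0.0147 and 0.0152 in simulations (r 0.495, 0.502 and 0.506). With the Het effects they were -0.0433, -0.0458 and -0.0388 (r -0.247, -0.288 and -0.277), where simulations gave -0.0148, -0.0151 and -0.0155 (r -0.496, -0.504 and -0.509).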
